A study of Gallus gallus with 4 samples.

How the data were processed

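Total RNA of 4 chick neural retina cultures, 2 treated with DAPT and 2 with DMSO, was hybridised to 1-colour Agilent chicken arrays. Per the labels' protocols, 100 ng of RNA per sample was amplified and labelled with Cy3, and the medium with DAPT or DMSO was renewed every 2 days. Group and replicate number came from the sample titles. Per the file headers, the deposited spot intensities were extracted by Agilent Feature Extraction 11.5.1.1, and the processed signal is a background-subtracted intensity on a linear scale. The authors' deposited value table holds the same processed signal intensity multiplied by 1 factor per array (1.41 and 1.50 in DMSO, 1.46 and 1.51 in DAPT), with column medians of 380 and 359 in DMSO and 350 and 336 in DAPT. That table is on a linear scale and not centred per gene, and what set the factors stays unknown. It served as an alternative.

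Spots that serve as controls were left out, as were spots with an outlier flag (7 and 4 in DMSO, 8 and 4 in DAPT), and no spot was saturated. The 75th percentile of the processed signal was 1604 and 1492 in DMSO and 1482 and 1412 in DAPT. Probes with more than 1 spot had a median coefficient of variation of 4.79% and 4.72% in DMSO and 4.25% and 5.04% in DAPT. The log2 processed signal minus each array's 75th percentile was analysed, after averaging the spots of a probe. Features were kept where the probe was well above background on both arrays of at least 1 group. For a named gene with several probes, the probe with the highest mean signal over all 4 arrays was used. Among 3363 symbol genes with over 1 kept probe, all probes had the same sign in 2875. The number of arrays, 2 per group, limits the precision.

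Accessions in the array design were named through a table of chicken genes of the assembly GRCg7b, used for names only, without coordinates, because the array's own annotation refers to an older build. Of 43603 probes, 11935 (27.4%) matched 5382 genes, 73 of them with a locus number as their only symbol, and 14692 probes had only an Ensembl transcript name and stayed unnamed. Of 37050 features, 32294 passed the filter, 5049 of them with a gene symbol. Of 897 entries in the gene lists 829 were found in the table, some through older symbols, so that a symbol such as PKLR, ALAS1, KRT13, KRT24 or SLC2A14 may stand for a related gene, and 438 distinct list genes were tested.

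Differences between DAPT and DMSO were tested with limma 3.58.1 (lmFit and eBayes, prior degrees of freedom 2.39) in R 4.3.3, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The labels state no pairing, so no block was used. The file headers place both arrays of replicate 1 on 1 slide and both of replicate 2 on another, so that a block for the slide and a block for the replicate number are the same fit. The 31 lists with at least 5 measured members were tested with limma's camera (preset correlation 0.01, against all other features, adjusted over the lists), with the median log2 fold change as their value. All 13 list calls were lost with a correlation estimated from the arrays, an estimate that rests on 2 residual degrees of freedom. The estimate was -0.052 for the lens membrane list and -0.0031 for the FGF response list, below the preset 0.01. Correlation between genes alone therefore cannot explain the lost calls. The list test, the 32 lists and the rule for named genes were fixed before the data were examined. Some genes belong to more than 1 list and count in each of them. The rule took every measured Notch target, up to 4 members per list past the threshold with the largest change, and the 12 symbol genes with the largest rise and the 12 with the largest fall whose DAPT arrays lay on one side of both DMSO arrays. CRYAA, CRYAB, CRYL1, MIP, DLL1 and MCM2 were named after their values were seen. Some genes that the rule took are not reported here.

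Alternatives were normexp background correction with offset 50 followed by the percentile or by quantile normalization, quantile normalization, median scaling, the authors' values, other filters on dim probes, all probes or the mean of a gene's probes, a trended robust prior, the slide block, each array left out, a 2-fold change as well, limma treat at a log2 fold change of 0.5, camera with an estimated correlation and fry. A mean spot signal was not used here, so normexp ran on the median signal and median background. Where all probes were tested, a gene counted as called if most of its probes passed, its adjusted p was their median, and each probe entered the list test as a feature of its own. Probes of 1 gene are not independent of each other, so the list p-values of that setting may be too small. Camera against only symbol genes was added after seeing the data.

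The tests were checked on simulated data with the arrays' own means, in which 200 of 32288 features were changed. The simulated spread within a group and the deviation shared by a slide were larger than those of the arrays. The rates below hold for that setting and are no estimate for these data. Without a block, 0 of 100 features changed by a log2 fold of 1 and 74 of 100 changed by 2 were called, with 0 unchanged features called. With the block, 98 and 100 of 100 were called, with 28 unchanged features called beside them, more than the nominal rate allows. With 8224 features changed, as many as were observed, 77.0% were recovered without the block, and 0.346% of the calls were false; with it the values were 97.7% and 4.47%. In the test of the list method, a list shifted by a log2 of 1 had a camera adjusted p of 1.68e-09, and 0 of 50 random lists were called. The simulated noise was independent between features and the lists were random. That check therefore says nothing about false calls for lists of genes that vary together.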

Results

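Gene expression was measured in cultures of chick neural retina, the layer of the embryonic eye that forms neurons and Müller glia, after long exposure to DAPT. DAPT inhibits γ-secretase, the protease that releases the active intracellular part of the Notch receptor. Retinas were taken at embryonic day 8 (stage 33), dissociated with trypsin and plated. DAPT at 10 µM, or an equal volume of its solvent DMSO, was present from day 2 until RNA was taken on day 12. Each group held 2 samples, each on 1 one-colour array. Each array carried 43803 spots apart from controls, of which 85.7% and 87.2% in DMSO and 89.3% and 87.7% in DAPT were well above background. The arrays of replicate 1 shared 1 slide and those of replicate 2 another, so every gene and list could also be compared within a slide. Nothing in the labels says that the samples of a group came from separate embryos or separate platings, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision throughout.

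The comparison of DAPT with DMSO asks which genes differ in retinal cultures after long exposure to the inhibitor. By itself it cannot tie a difference to Notch signalling. The largest rises were in lens genes and the largest falls in matrix enzymes, elastin and growth factor genes. BFSP1 and BFSP2, which form the beaded filaments of lens fibre cells, rose by 9.21 ± 0.27 and 6.60 ± 0.12 (log2 fold change ± SE, n = 2 arrays per group, as for all genes here). Normalised log2 signal of BFSP1 was -4.10 ± 0.54 in DMSO and 5.11 ± 0.021 in DAPT (SD, n = 2), relative to each array's 75th percentile. CRYBB1 rose by 7.99 ± 0.19, CRYBA2 by 7.83 ± 0.22 and CRYBA4 by 5.81 ± 0.22, all 3 of them β-crystallins. RBM24, an RNA-binding protein of muscle and lens, rose by 5.60 ± 0.14, CALCA, which encodes calcitonin and the peptide CGRP, by 6.40 ± 0.26, VSIG1, an adhesion protein of the immunoglobulin family, by 6.19 ± 0.12, and GTF2A1L, a germ-cell form of a general transcription factor, by 6.75 ± 0.22. CTLA4, an inhibitory receptor of T cells, was not well above background in DMSO and was at least 77.7-fold higher in DAPT, under the floor defined in the next paragraph. The adjusted p of these genes lay between 8.99e-04 and 0.00155 in limma. With normexp background correction, CTLA4 was at 3.40, GTF2A1L was at 4.21 and CRYBA4 was at 3.87.

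In the other direction, the matrix metalloproteinases MMP7 and MMP13 were at -6.09 ± 0.17 and -5.94 ± 0.69, and MMP10 was at least 19.3-fold lower. ELN, which encodes elastin, was at -6.29 ± 0.56. AREG, a ligand of the EGF receptor, was at -6.21 ± 0.21, and EREG, another, was at least 27.5-fold lower. FST, which encodes the activin-binding protein follistatin, was at -4.71 ± 0.12, GLRX, a glutaredoxin, at -5.15 ± 0.16, SLA, an adaptor related to Src, at -5.03 ± 0.13, and GLT8D2, of a glycosyltransferase family, at -5.46 ± 0.15. FLI1, an ETS transcription factor, was at -6.07 ± 0.12, but its other probe was at -0.75, and with all probes tested only 1 of its 2 probes passed. A fold given as at least N set the bright group's mean against, on each dim array, the higher of the probe's own signal and the lowest signal among probes well above background. That floor is a lenient one, so such a fold is no guaranteed minimum. Normexp correction gave smaller differences for every gene reported this way. After normexp correction FLI1 was at -3.21, MMP10 was at -1.46, MMP7 was at -3.86, MMP13 was at -3.25, GLT8D2 was at -3.11, EREG was at -1.60 and SLA was at -2.55.

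**Figure D1:**
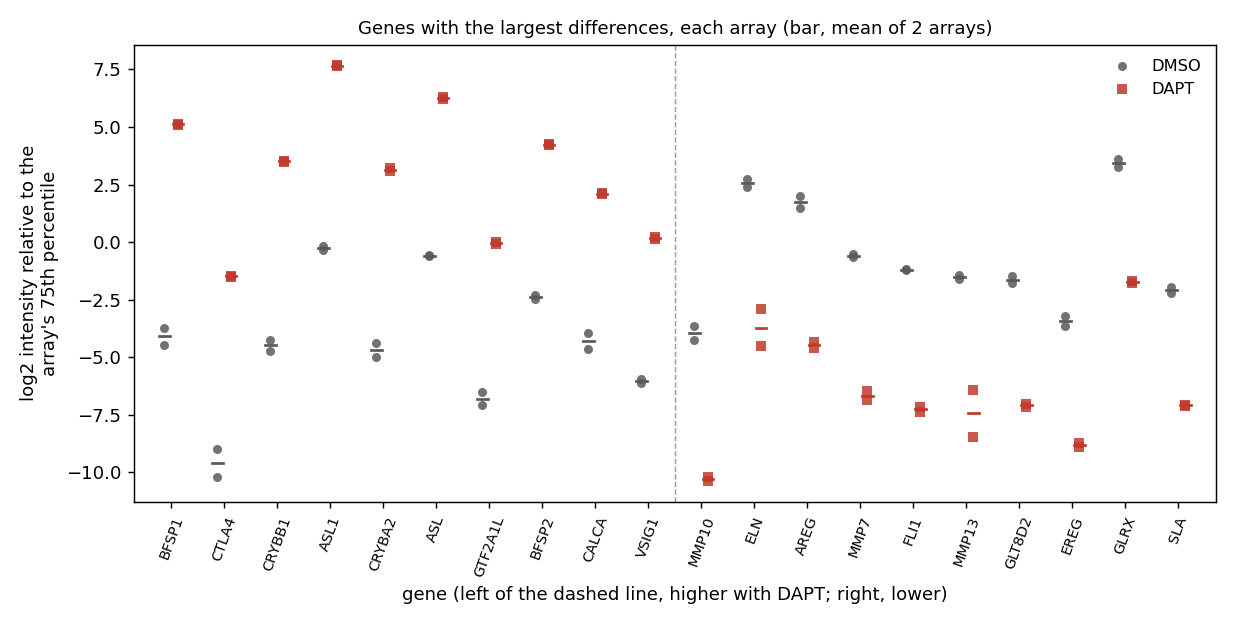
Normalised log2 signal on each of the 4 arrays (points, 2 per group, with a bar at their mean) of the 10 symbol genes with the largest rise and the 10 with the largest fall in DAPT, relative to each array's 75th percentile. The rule that chose these genes required both DAPT arrays to lie on the same side of both DMSO arrays.

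Over all 32294 features tested, 3991 were higher and 4234 lower in DAPT at an adjusted p under 0.05, and among the 5049 of them with a gene symbol 716 were higher and 699 lower. At least a 2-fold change as well was seen for 298 symbol genes higher and 410 lower, and at least a 10-fold change for 37 and 47. With the slide as a block, 6858 features were higher and 6006 lower, and all 8225 calls of the unblocked fit were kept. Without DAPT replicate 1 the counts were 1417 and 2069, and without DAPT replicate 2 they were 1345 and 2032. The median log2 fold change over all features was 0.061. Replicates correlated at 0.994 in DMSO and 0.996 in DAPT across features, which are not independent of each other, and arrays of different groups at 0.962 to 0.966. Exact permutation of 2 against 2 arrays cannot give a two-sided p below 0.333.

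Of the 19 genes in the Notch target list only 4 were measured under a gene name, too few for a list test. Other members may lie among the 14692 probes that stayed unnamed, which holds for every list and family here. Of these, 3 fell and 1 rose (the same 3 and 1 adjusted over the list alone). HES4, a transcriptional repressor of the hairy family, was at -0.83 ± 0.14 (adjusted p = 0.0191), and LFNG, the Lunatic fringe glycosyltransferase that modifies Notch, at -1.01 ± 0.11 (adjusted p = 0.00674). CCND1, which encodes cyclin D1, was at -0.97 ± 0.12 (adjusted p = 0.00933). GATA3, a transcription factor, rose by 1.80 ± 0.30 (adjusted p = 0.0184), by 2.24 on slide 1 and 1.36 on slide 2. In the list of Notch ligands, receptors and modifiers, 1 of 10 measured members rose and 1 fell (1 and 1 adjusted over the list alone). They were NEURL1, a ubiquitin ligase acting on Notch ligands, at 0.67 ± 0.10, and the receptor NOTCH2 at -1.18 ± 0.10. The ligand DLL1 was at -0.19 ± 0.27 and did not pass. The list's median was -0.068 (0.067 on slide 1, -0.086 on slide 2), and camera, limma's test of a list against the other features, gave an adjusted p of 0.526. The call was lost without DAPT replicate 1 for LFNG, GATA3, CCND1, HES4 and NEURL1 (adjusted p = 0.0531 to 0.127), without DAPT replicate 2 for GATA3, HES4 and NEURL1 (adjusted p = 0.0560 to 0.106), without DMSO replicate 2 for NEURL1 (adjusted p = 0.0511).

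Lens crystallins, the abundant soluble proteins of the lens, rose almost as a whole. Of 13 measured members 12 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 5.11 (5.44 on slide 1, 4.99 on slide 2). Camera gave an adjusted p of 4.72e-11, and adjusted p = 0.440 with an estimated correlation. CRYAA and CRYAB, the α-crystallins, rose by 5.11 ± 0.31 and 4.61 ± 0.23. The δ-crystallin genes ASL1 and ASL were at 7.90 ± 0.11 and 6.83 ± 0.10, but their sequences are near-identical and the signal cannot be divided between them with certainty. CRYL1, a crystallin-related enzyme, was at 0.22 ± 0.10 and did not pass. In the same arrays the fibroblast list had a median of -2.49.

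Among lens membrane, cytoskeleton and fibre genes, 9 of 16 measured members rose and 1 fell (10 and 1 adjusted over the list alone). GJA3, a connexin of lens fibres, rose by 3.34 ± 0.26 and FABP5, a fatty acid carrier, by 2.55 ± 0.13. MIP, the main water channel of lens fibres, was at -0.11 ± 0.40 and did not pass. The list's median was 0.80 (0.77 on slide 1, 0.80 on slide 2), with adjusted p = 0.00279 and adjusted p = 0.440 with an estimated correlation, and the median was 0.50 under normexp. Of lens transcription factors, 9 of 18 measured members rose and 4 fell (9 and 4 adjusted over the list alone). SOX1, which regulates crystallin genes, was not well above background in DMSO and was at least 3.39-fold higher in DAPT. SOX3 rose by 2.00 ± 0.10, with probes from 0.53 to 2.08, while TFAP2A, also a member of the amacrine list, and PITX1 were at -1.84 ± 0.12 and -1.84 ± 0.26. As a list the factors did not pass (median 0.46, with 0.40 on slide 1 and 0.52 on slide 2, camera adjusted p = 0.0681). They did pass with the authors' values, no filter and fry (adjusted p = 0.0435, 0.0450 and 0.0184) and without DMSO replicate 1, DMSO replicate 2 and DAPT replicate 1 in turn (adjusted p = 0.0394, 0.0474 and 0.0399). Fry is a rotation test of the list alone. Under normexp, GJA3 was at 1.29, SOX1 was at 0.49 and PITX1 was at -1.04.

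Photoreceptor genes were mostly lower: 19 of 28 measured members fell and 2 rose (19 and 4 adjusted over the list alone). OPN1MSW, a cone opsin, was at -3.19 ± 0.24, ARR3, the cone arrestin, at -1.68 ± 0.10, and IMPG1, a proteoglycan of the matrix around photoreceptors, at -1.59 ± 0.19. SLC24A2, a sodium, calcium and potassium exchanger of cones, rose by 1.62 ± 0.13. The list's median was -1.01 (-1.14 on slide 1, -0.83 on slide 2), with adjusted p = 4.11e-05 and adjusted p = 0.530 with an estimated correlation, and the median was -0.60 under normexp. Among amacrine cell genes 9 of 16 fell and 1 rose (11 and 1 adjusted over the list alone). The transcription factor TFAP2B was at -1.89 ± 0.14 and the calcium-binding protein CALB2 at -1.68 ± 0.13, whereas the neuropeptide gene NPY rose by 3.86 ± 0.37. This list's median was -1.11 (-1.51 on slide 1, -1.02 on slide 2), with adjusted p = 6.25e-04 and adjusted p = 0.440 with an estimated correlation, and the median was -0.64 under normexp. The fibroblast list was lower in the same arrays (median -2.49). With normexp background correction, OPN1MSW was at -1.87.

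Pan-neuronal genes went both ways, with 8 of 21 lower and 2 higher (10 and 2 adjusted over the list alone). SCG3, a granin of secretory granules, was at -2.20 ± 0.14 and STMN2, a regulator of microtubules, at -2.07 ± 0.16. NEFM, a neurofilament protein, rose by 2.12 ± 0.18, and DCX, the doublecortin of young neurons, by 1.85 ± 0.19. The median was -0.41 (-0.51 on slide 1, -0.28 on slide 2), with camera adjusted p = 0.00446, adjusted p = 0.530 with an estimated correlation, and 0.0767 by fry. The fibroblast list had a median of -2.49 beside it. For retinal ganglion cell genes, 2 of 11 measured members rose and 5 fell (2 and 5 adjusted over the list alone): RBPMS2, an RNA-binding protein, was at -2.27 ± 0.10, CHRNB3, a nicotinic receptor subunit, at -1.70 ± 0.13 (its other probe -0.48, and with all probes tested only 1 of 2 passed), and SNCG, γ-synuclein, rose by 1.20 ± 0.14. That list did not pass (median -0.081, with -0.16 on slide 1 and -0.0038 on slide 2, camera adjusted p = 0.231), except with fry (adjusted p = 0.0251), and its median was 0.21 without DMSO replicate 1, 0.14 without DAPT replicate 2 and 0.067 with all probes or probe means. For bipolar cell genes, 1 of 12 measured members rose and 0 fell (1 and 0 adjusted over the list alone), VSX1, a homeobox gene, by 1.39 ± 0.18. They did not pass as a list (median 0.41, with 0.25 on slide 1 and 0.56 on slide 2, camera adjusted p = 0.0747), but did with all probes tested (adjusted p = 0.0164) and without DMSO replicate 1 and DAPT replicate 1 in turn (adjusted p = 0.0240 and 0.0492). For horizontal cell genes, 1 of 6 measured members rose and 2 fell (1 and 4 adjusted over the list alone): PROX1, a homeobox gene, rose by 1.52 ± 0.13 and CALB1, calbindin, was at -1.96 ± 0.11, with probes up to -0.65 (median -0.34, with -0.27 on slide 1 and -0.41 on slide 2, camera adjusted p = 0.209). The horizontal cell list passed with fry (adjusted p = 0.0267). PROX1 is also a member of the lens transcription factor list.

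Of the proneural and neurogenic transcription factors, 2 of 11 measured members rose and 3 fell (5 and 4 adjusted over the list alone). GADD45G, a growth arrest gene, rose by 0.58 ± 0.13, while EBF1 and CBFA2T3 were at -1.58 ± 0.15 and -0.79 ± 0.11. The list's median was -0.18 (-0.058 on slide 1, -0.00015 on slide 2), its mean 0.089 and its test direction down (adjusted p = 0.653). Among retinal progenitor genes, 3 of 20 measured members rose and 5 fell (4 and 5 adjusted over the list alone). EGFR, the EGF receptor, was at -2.14 ± 0.18, the secreted Wnt modulator SFRP2 at -1.96 ± 0.10 and SOX8 at -1.14 ± 0.14, and DKK3, a secreted glycoprotein, rose by 1.07 ± 0.13. The median was 0.094 (-0.015 on slide 1, 0.10 on slide 2), the mean -0.15 and the test direction down (adjusted p = 0.524). Of Müller glia genes, 6 of 28 measured members rose and 6 fell (10 and 9 adjusted over the list alone). AQP4, the water channel of glia, was at -4.48 ± 0.52, COL9A1, a collagen, at -3.99 ± 0.14 and TIMP3, a metalloproteinase inhibitor, at -2.93 ± 0.11. RLBP1, the retinaldehyde-binding protein of Müller glia and pigment epithelium, rose by 1.91 ± 0.33. This list's median was 0.22 (0.011 on slide 1, 0.22 on slide 2), its mean -0.28 and its test direction down (adjusted p = 0.771). Calls at this threshold ended without DAPT replicate 1 for SOX8, DKK3, RLBP1, CBFA2T3 and GADD45G (adjusted p = 0.0502 to 0.120), without DAPT replicate 2 for RLBP1, CBFA2T3 and GADD45G (adjusted p = 0.0628 to 0.246), without DMSO replicate 1 for GADD45G (adjusted p = 0.119), without DMSO replicate 2 for GADD45G (adjusted p = 0.0696). After normexp correction EBF1 was at -0.92 and AQP4 was at -1.58. CBFA2T3 also missed the threshold with all probes tested (adjusted p = 0.0897). GADD45G also missed the threshold with the authors' values and no filter (adjusted p = 0.0523 and 0.0666).

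Of the pigment epithelium and melanin genes, 8 of 16 measured members rose and 4 fell (11 and 4 adjusted over the list alone). DCT and TYR, enzymes of melanin synthesis, rose by 3.35 ± 0.29 and 3.25 ± 0.25, and RGR, an opsin of pigment epithelium and Müller glia, by 2.31 ± 0.25, whereas the endothelin receptor EDNRB2 was at -3.54 ± 0.19. The list did not pass (median 0.80, with 0.63 on slide 1 and 1.03 on slide 2, camera adjusted p = 0.119), but did with all probes tested (adjusted p = 0.0481) and without DMSO replicate 1, DMSO replicate 2 and DAPT replicate 1 in turn (adjusted p = 0.0355, 0.0489 and 0.0432). In the list of ciliary margin and iris genes, 3 of 15 measured members rose and 7 fell (5 and 8 adjusted over the list alone). WFDC1, a secreted protease-inhibitor-like protein, was at -2.85 ± 0.11 and the homeobox gene MSX1 rose by 2.56 ± 0.12 (median -0.66, with -0.81 on slide 1 and -0.41 on slide 2, camera adjusted p = 0.128). Ciliary margin genes passed with normexp and the percentile, the stricter filter, all probes tested and fry (adjusted p = 0.0428, 0.0449, 7.74e-05 and 0.0184). Under normexp, TYR was at 1.06.

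Cell proliferation genes rose together, 26 of 31 measured members, with 1 lower (26 and 1 also adjusted over the list alone). KIF20A, a kinesin of cell division, rose by 1.22 ± 0.16, the mitotic kinase genes PBK and BUB1 by 1.13 ± 0.10 and 1.11 ± 0.12, and CDC20, an activator of the anaphase-promoting complex, by 1.11 ± 0.17. MCM2, a subunit of the replicative helicase, was at -0.56 ± 0.13. The list's median was 0.82 (0.83 on slide 1, 0.79 on slide 2), with adjusted p = 1.05e-08 and adjusted p = 0.440 with an estimated correlation, beside a fibroblast list median of -2.49. The threshold was missed without DAPT replicate 1 for CDC20 (adjusted p = 0.0543), without DAPT replicate 2 for KIF20A and CDC20 (adjusted p = 0.0562 to 0.0758).

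FGF signal response genes were lower, 6 of 12 (7 adjusted over the list alone), with none higher in limma. SPRY1 and SPRY3, feedback inhibitors of receptor tyrosine kinases, were at -1.86 ± 0.10 and -2.58 ± 0.10, the ETS factor ETV1 at -1.60 ± 0.14 and IL17RD, another feedback inhibitor, at -1.34 ± 0.11. The median was -0.69 (-0.59 on slide 1, -0.80 on slide 2), with adjusted p = 6.79e-04 and adjusted p = 0.440 with an estimated correlation. In these arrays the fibroblast list was lower too (median -2.49). Of BMP and TGF-beta response genes, 2 of 16 measured members rose and 7 fell (3 and 10 adjusted over the list alone). TGFBI, a matrix protein induced by TGF-beta, was at -3.14 ± 0.13 and MSX2 at -1.67 ± 0.15. In contrast, MSX1 rose by 2.56 ± 0.12 and ID2, an inhibitor of bHLH factors, by 1.46 ± 0.12. That list's median was -0.53 (-0.55 on slide 1, -0.41 on slide 2), with adjusted p = 0.0421 and adjusted p = 0.440 with an estimated correlation, and the median was -0.30 under normexp. It no longer passed with the authors' values, no filter, all probes tested and probe means (adjusted p = 0.0644, 0.0525, 0.280 and 0.0899) and without DMSO replicate 2 and DAPT replicate 1 in turn (adjusted p = 0.0978 and 0.0750). Of Wnt response genes, 3 of 14 measured members rose and 5 fell (3 and 5 adjusted over the list alone). WIF1, a secreted Wnt inhibitor, was at -2.84 ± 0.31 and APCDD1, another Wnt inhibitor, at -1.09 ± 0.22, and the ligand WNT2B rose by 1.11 ± 0.27 (median -0.19, with -0.17 on slide 1 and -0.25 on slide 2, camera adjusted p = 0.231). Calls were lost without DAPT replicate 1 for APCDD1 and WNT2B (adjusted p = 0.104 to 0.119), without DAPT replicate 2 for APCDD1 and WNT2B (adjusted p = 0.0962 to 0.164). With normexp background correction, SPRY3 was at -1.43 and WNT2B was at 0.70. WNT2B also missed the threshold with quantile normalization, the authors' values, no filter and probe means (adjusted p = 0.0577, 0.0569, 0.0764 and 0.0506).

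Fibroblast and mesenchymal genes were among the lists with the lowest values: 17 of 21 measured members fell and 1 rose (17 and 2 adjusted over the list alone). The collagen genes COL6A3 and COL3A1 were at -4.29 ± 0.17 and -4.17 ± 0.10, and POSTN, which encodes the matrix protein periostin, at -4.14 ± 0.13. TCF21, a transcription factor of mesenchyme, rose by 4.57 ± 0.098, with probes from 2.18 to 4.57. The median was -2.49 (-2.65 on slide 1, -2.81 on slide 2), with adjusted p = 1.05e-08 and adjusted p = 0.440 with an estimated correlation. In the extracellular matrix and basement membrane list, 13 of 16 fell and 0 rose (13 and 0 also adjusted over the list alone). FN1, fibronectin, was at -3.62 ± 0.20, TNC, tenascin C, at -3.44 ± 0.16 and the basement membrane collagen COL4A1 at -3.19 ± 0.10. This list's median was -1.50 (-1.28 on slide 1, -1.73 on slide 2), with adjusted p = 1.05e-08 and adjusted p = 0.440 with an estimated correlation. After normexp correction TCF21 was at 2.32.

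Lists for other cell types that the dissociated tissue could hold gave mixed values. Of endothelial genes, 0 of 8 measured members rose and 3 fell (0 and 3 adjusted over the list alone): besides FLI1, they were the ETS factor ERG at -2.24 ± 0.17 and the VEGF receptor FLT1 at -1.62 ± 0.10. The median was -0.71 (-0.98 on slide 1, -0.44 on slide 2), with adjusted p = 0.00446 and adjusted p = 0.440 with an estimated correlation, and the call was lost with all probes tested and probe means (adjusted p = 0.0822 and 0.0899). The endothelial median was -0.33 without DMSO replicate 1, -1.09 without DMSO replicate 2 and -0.34 under normexp. Of macrophage and microglia genes, 1 of 16 measured members rose and 3 fell (1 and 3 adjusted over the list alone). TREM2, a receptor of microglia, was at least 4.45-fold lower, HAVCR1 was at -2.46 ± 0.14 and LYZ, lysozyme, at -0.93 ± 0.11, and CD74, the invariant chain, rose by 1.19 ± 0.11 (median -0.0036, with -0.012 on slide 1 and -0.049 on slide 2, camera adjusted p = 0.264). Of oligodendrocyte lineage genes, 1 of 8 measured members rose and 4 fell (1 and 4 adjusted over the list alone). MBP, a myelin protein, was at -2.97 ± 0.19, the myelin enzyme CNP at -1.85 ± 0.19 and the PDGF receptor PDGFRA at -2.12 ± 0.16. That list did not pass (median -0.47, with -0.52 on slide 1 and -0.56 on slide 2, camera adjusted p = 0.0681). It did pass with normexp and the percentile, normexp and quantiles, the stricter filter, all probes tested and the slide as a block (adjusted p = 0.0303, 0.0391, 0.0138, 7.61e-04 and 0.0488) and without DMSO replicate 2 and DAPT replicate 1 in turn (adjusted p = 0.0297 and 0.0242). Of erythroid genes, 3 of 11 measured members rose and 1 fell (4 and 2 adjusted over the list alone): GYPC, a glycophorin, rose by 2.77 ± 0.18, the carbonic anhydrase CA2 by 1.20 ± 0.20 and TFRC, the transferrin receptor, by 0.73 ± 0.13, and ALAS1, of haem synthesis, was at -0.44 ± 0.10 (median 0.35, with 0.25 on slide 1 and 0.40 on slide 2, camera adjusted p = 0.264). CA2 is also a member of the Müller glia list. Of surface ectoderm, cornea and keratin genes, 3 of 11 measured members rose and 2 fell (5 and 2 adjusted over the list alone). CLDN1, a tight junction protein, rose by 1.15 ± 0.12 and EPCAM, an epithelial adhesion protein, by 1.00 ± 0.17, and KERA, keratocan of the corneal stroma, and KRT14 were at -2.61 ± 0.18 and -0.92 ± 0.22. The median was -0.0036 (0.0098 on slide 1, -0.017 on slide 2), the mean 0.15 and the test direction up (adjusted p = 0.698). The call was lost without DAPT replicate 1 for CA2, LYZ, EPCAM, TFRC, KRT14 and ALAS1 (adjusted p = 0.0596 to 0.296), without DAPT replicate 2 for CA2, EPCAM, KRT14, TFRC and ALAS1 (adjusted p = 0.0806 to 0.223), without DMSO replicate 1 for TFRC and ALAS1 (adjusted p = 0.0536 to 0.0892), without DMSO replicate 2 for KRT14 and ALAS1 (adjusted p = 0.0730 to 0.122). Under normexp, ERG was at -1.26, FLT1 was at -0.25 (adjusted p = 0.0908, no longer past), TREM2 was at -0.38, LYZ was at -0.56, TFRC was at 0.38 (adjusted p = 0.0531, no longer past), MBP was at -1.75, EPCAM was at 0.32 (adjusted p = 0.0590, no longer past) and KRT14 was at -0.48 (adjusted p = 0.108, no longer past). ALAS1 also missed the threshold with median scaling and no filter (adjusted p = 0.0599 and 0.0711). KRT14 also missed the threshold with quantile normalization, median scaling and no filter (adjusted p = 0.0747, 0.0525 and 0.0721).

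Cholesterol synthesis genes rose as a group, 10 of 12 measured members with 0 lower (11 and 0 adjusted over the list alone). HMGCS1, an early enzyme of the pathway, rose by 2.01 ± 0.11, SQLE by 1.95 ± 0.12 and MSMO1 by 1.72 ± 0.11. The median was 1.54 (1.45 on slide 1, 1.56 on slide 2), with adjusted p = 1.52e-06 and adjusted p = 0.440 with an estimated correlation, beside a fibroblast list median of -2.49. Of heat shock genes, 4 of 14 measured members rose and 0 fell (7 and 0 adjusted over the list alone). The small heat shock protein gene HSPB1 rose by 1.13 ± 0.14, HSPH1 by 0.68 ± 0.10, HSF2, a heat shock transcription factor, by 0.55 ± 0.099 and DNAJA1, a co-chaperone, by 0.47 ± 0.10. The median was 0.34 (0.33 on slide 1, 0.32 on slide 2), with adjusted p = 0.00843 and adjusted p = 0.507 with an estimated correlation, and the call was lost with normexp and quantiles and quantile normalization (adjusted p = 0.124 and 0.143). Calls at this threshold ended without DAPT replicate 1 for HSPH1, HSF2 and DNAJA1 (adjusted p = 0.104 to 0.194), without DAPT replicate 2 for HSPB1, HSPH1, HSF2 and DNAJA1 (adjusted p = 0.0506 to 0.275), without DMSO replicate 1 for HSF2 and DNAJA1 (adjusted p = 0.0671 to 0.105), without DMSO replicate 2 for HSF2 and DNAJA1 (adjusted p = 0.0630 to 0.0860). DNAJA1 also missed the threshold with quantile normalization, the authors' values and no filter (adjusted p = 0.0683, 0.0535 and 0.0622).

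The remaining lists did not pass with the settings used throughout. Of endoplasmic reticulum and integrated stress genes, 2 of 12 measured members rose and 3 fell (2 and 3 adjusted over the list alone), with CHAC1, induced by that response, at -1.75 ± 0.13, ASNS, asparagine synthetase, at -0.99 ± 0.19, DNAJB9 at -0.58 ± 0.099 and the chaperone CANX higher by 0.67 ± 0.11 (median -0.15, with -0.14 on slide 1 and -0.15 on slide 2, camera adjusted p = 0.227). Stress genes passed with normexp and quantiles and all probes tested (adjusted p = 0.0465 and 0.0176). Of apoptosis and p53 target genes, 1 of 14 measured members rose and 5 fell (2 and 6 adjusted over the list alone), with MDM2, the ubiquitin ligase of p53, at -1.32 ± 0.19, the survival gene BCL2 at -1.13 ± 0.11, the cell cycle inhibitor CDKN1A at -0.82 ± 0.12 and CASP6 at -0.77 ± 0.12 (median -0.087, with -0.042 on slide 1 and -0.14 on slide 2, camera adjusted p = 0.143). The apoptosis list passed with fry (adjusted p = 0.0184). Of glycolysis and hypoxia genes, 3 of 22 measured members rose and 2 fell (3 and 2 adjusted over the list alone). VEGFA, an angiogenic factor, was at -1.56 ± 0.16, the glycolytic enzyme ENO1 rose by 0.98 ± 0.10, LDHA by 0.95 ± 0.12 (probes from 0.33 to 1.63) and PKLR, a pyruvate kinase, by 0.63 ± 0.13 (median 0.21, with 0.26 on slide 1 and 0.18 on slide 2, camera adjusted p = 0.219). Glycolysis genes passed with all probes tested (camera adjusted p = 8.42e-04), where several probes of 1 gene count as separate members. The threshold was missed without DAPT replicate 1 for LDHA, MDM2, CANX, CDKN1A, ASNS, CASP6, DNAJB9 and PKLR (adjusted p = 0.0508 to 0.169), without DAPT replicate 2 for ENO1, ASNS, LDHA, CASP6, CDKN1A, DNAJB9, CANX and PKLR (adjusted p = 0.0507 to 0.158), without DMSO replicate 1 for DNAJB9, CANX and PKLR (adjusted p = 0.0606 to 0.0738), without DMSO replicate 2 for CANX, CASP6, DNAJB9 and ASNS (adjusted p = 0.0536 to 0.0664). PKLR also missed the threshold with no filter (adjusted p = 0.0522).

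**Figure D2:**
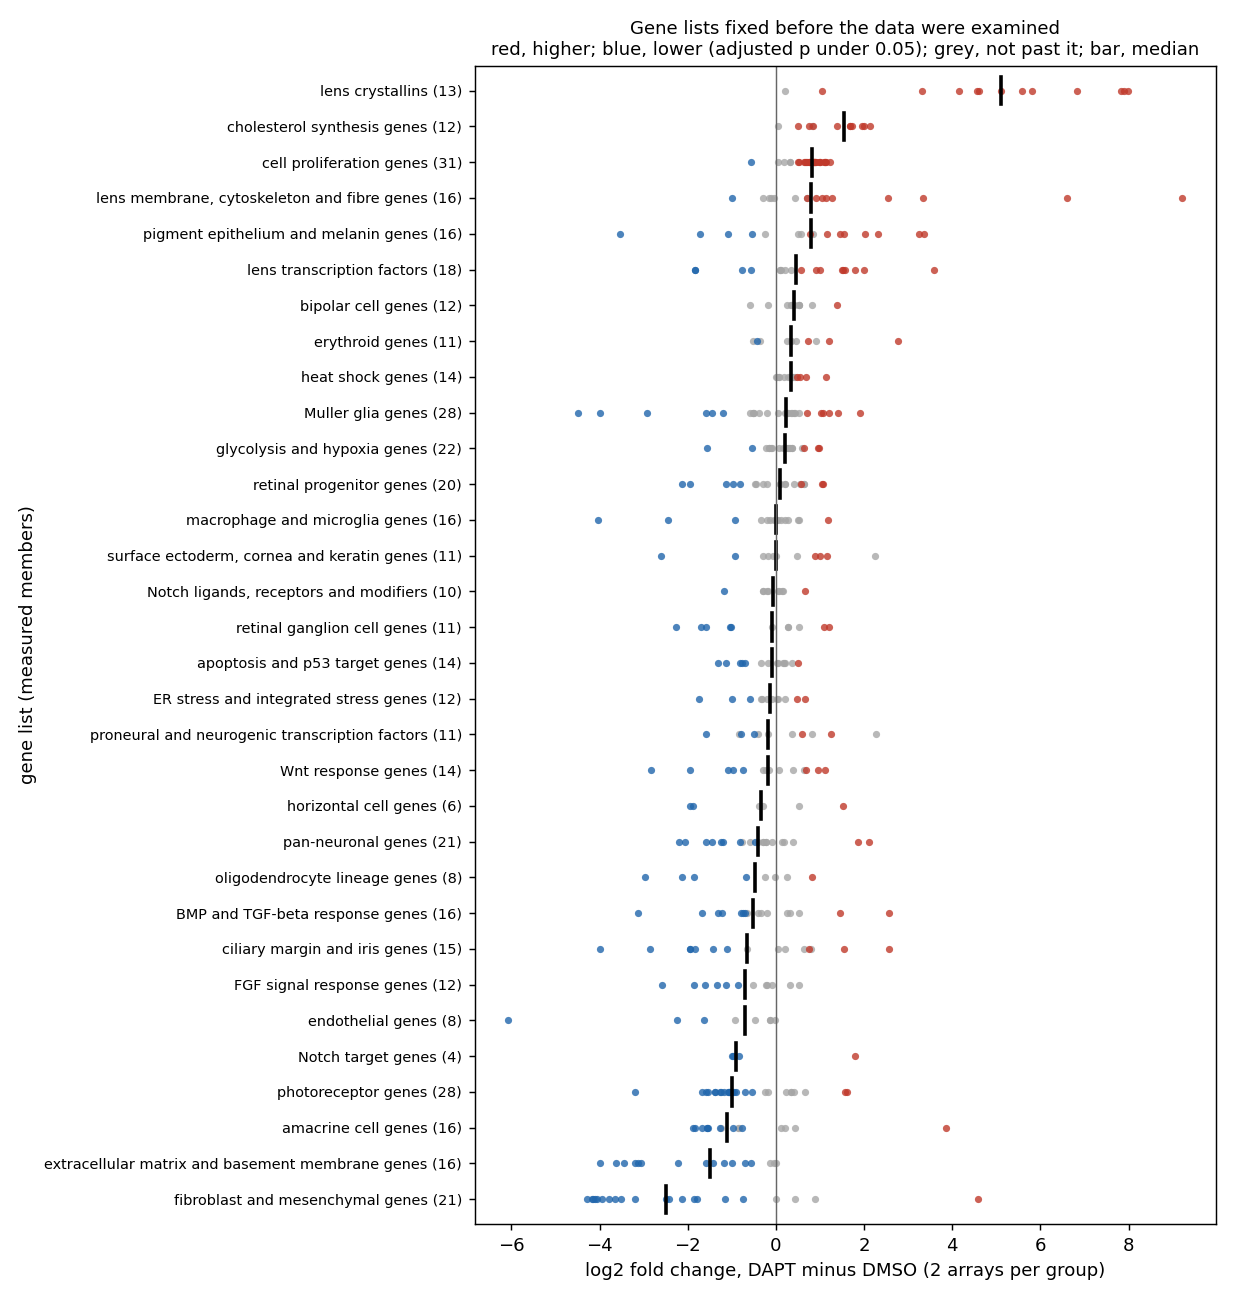
Log2 fold change of DAPT over DMSO of each measured member of each gene list (points, red for members past the adjusted p as higher, blue as lower, grey for the others), with a bar at the list's median. The crystallin list has a median of 5.11 and the fibroblast list a median of -2.49.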

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

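Camera against only symbol genes was the one alternative chosen after the data were seen. In all 130 genes named by the rule, both DAPT arrays lay on one side of both DMSO arrays. Leaving out an array or adding the block therefore could not change the direction of these genes. Of the 148 named genes (130 by the rule, the others of families chosen later), none changed direction in any setting run; 107 passed with each array left out in turn and 134 in every setting that kept all arrays. Lost calls numbered 37 without DAPT replicate 1 and 34 without DAPT replicate 2, where the lone array is assumed to vary like the other group and fewer degrees of freedom remain. The counts of 3991 features higher and 4234 lower became 6858 and 6006 with the replicate block, which is also the slide block, 1569 and 2293 with at least a 2-fold change as well, and 1272 and 1856 by limma treat. Leaving out 1 array gave 1345 to 3078 higher and 2032 to 3360 lower. The share of higher calls was 48.5%, and 41.8% with the authors' values. Besides the oligodendrocyte list, whose adjusted p became 0.0488, the block changed no list's call. Replicate differences of the groups correlated at 0.583 over features, but the labels state no pairing.

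With an estimated correlation all 13 list calls were lost, at unchanged medians: crystallins 5.11, lens membrane 0.80, pan-neuronal -0.41, amacrine -1.11, photoreceptor -1.01, proliferation 0.82, FGF response -0.69, BMP and TGF-beta -0.53, fibroblast -2.49, endothelial -0.71, heat shock 0.34, cholesterol 1.54 and matrix -1.50. For lens membrane and FGF response genes the estimate lay below the preset 0.01, so correlation alone cannot explain the losses. By fry, pan-neuronal genes (-0.41) did not pass. Lens factors (0.46), ganglion (-0.081), horizontal (-0.34), ciliary margin (-0.66) and apoptosis (-0.087) genes did.

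Normexp turned the Notch ligand median to 0.0074 with the percentile and 0.0041 with quantiles, passed oligodendrocyte (-0.38 and -0.37), ciliary margin (-0.63, percentile) and ER stress (-0.29, quantiles) genes, and with quantiles lost heat shock (0.18). Quantile normalization lost heat shock (0.21) and turned macrophage (0.025) and keratin (0.061) medians, as median scaling did (0.015 and 0.015). The authors' values passed lens factors (0.40) and lost BMP and TGF-beta (-0.59). With no filter lens factors passed (0.46) and BMP and TGF-beta did not (-0.53); with the stricter filter oligodendrocyte (-0.69) and ciliary margin (-0.89) genes passed. With all probes bipolar (0.41), pigment (0.91), oligodendrocyte (-0.42), ciliary margin (-0.66), ER stress (-0.20) and glycolysis (0.32) genes passed. That setting counts several probes of 1 gene as separate members, so its passes are weak evidence. With all probes and with probe means, ganglion genes turned to 0.067, and BMP and TGF-beta (-0.49) and endothelial (-0.57) genes did not pass. The block gave -0.47 for oligodendrocyte genes.

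Leaving out 1 array gave medians of -0.075 to 0.063 for Notch ligands, 0.42 to 0.50 for lens factors, -0.38 to 0.21 for ganglion, 0.25 to 0.58 for bipolar, -0.00083 to 0.061 for progenitor and 0.64 to 1.09 for pigment genes, -0.59 to -0.42 for BMP and TGF-beta, -0.24 to 0.30 for macrophage, -0.69 to -0.25 for oligodendrocyte and -0.036 to 0.24 for keratin genes. Endothelial medians lay between -1.09 and -0.33, erythroid between 0.024 and 0.66 and Müller glia between 0.031 and 0.32. The cause of these changes was not tested. Normexp moved 35 of the 148 named genes by over 1.5 times, all towards 0, as its added offset does to dim probes by construction, and among called lists it moved the medians of lens membrane (0.50 with the percentile, 0.44 with quantiles), amacrine (-0.64 and -0.63), photoreceptor (-0.60 and -0.60), BMP and TGF-beta (-0.30 and -0.28) and endothelial (-0.34 and -0.34) genes. Bounds were given only for genes with no probe well above background on either array of a group. On DAPT replicate 2, MMP13 and AQP4 (-8.44 and -8.26) lay below every signal well above background, so their fold changes are uncertain too.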

Other observations

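The families in the next paragraph and all tests below were chosen after results were seen, except the spike-in test, whose prediction was written before its value. That prediction took a share above 0.05 as fitting the slide's handling, and it was met; the verdict was changed to open after the value was seen, since the share missed 0.05 narrowly with 8 spike-ins, whose spread lay below that of the features. The verdict on cell content was also changed to open after its value was seen, since lists that miss a threshold exclude nothing. The scaling test replaced an earlier one that subtracted the median of all features and so could not respond to scaling; its values were known when it was chosen, and the bound of -0.5 was kept from the earlier test. The test of dilution is the third one run: the first took a pair of lists picked from its values and was dropped, the second, of the spread over all lists, missed its threshold and is given beside the third, which was chosen with list medians and both earlier results known.

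Matrix metalloproteinases, which degrade the extracellular matrix, were lower with all arrays kept, where all 7 measured members passed, among them MMP27 at -4.63 ± 0.14, MMP9 at -3.01 ± 0.21 and MMP16 at -1.59 ± 0.15 (log2 fold change ± SE, n = 2 arrays per group, limma adjusted p = 9.06e-04, 0.00265 and 0.00469). Of 6 ligands of the EGF receptor, 3 fell and 0 rose, with EPGN at -1.08 ± 0.12 beside AREG at -6.21 and EREG, which was at least 27.5-fold lower. HBEGF, TGFA and BTC did not pass (0.27, 0.41 and 0.44). Of 14 Wnt ligands 6 rose and 3 fell. WNT7A and WNT7B rose by 3.36 ± 0.13 and 3.25 ± 0.14 and WNT5B by 1.82 ± 0.15, whereas WNT6 was at -2.00 ± 0.099 and WNT4 at -1.40 ± 0.20. Of 13 FGF ligands 3 rose and 1 fell: FGF7 and FGF1 rose by 2.20 ± 0.23 and 1.56 ± 0.13, FGF16 was at least 9.12-fold higher and FGF14 was at -0.90 ± 0.11. The receptor FGFR3 rose by 4.84 ± 0.14, and FGFR1 and FGFR2, at 0.44 and 0.25, did not pass. No called member of these families changed sign under any scaling. The scalings gave a median of all features from only -0.0036 to 0.081, so they could hardly have turned such values. Calls were lost without DAPT replicate 1 for WNT4, FGF14, MMP2, WNT10A, WNT2B and WNT11 (adjusted p = 0.0531 to 0.181), without DAPT replicate 2 for FGF14, WNT5A, WNT11, MMP2, WNT10A and WNT2B (adjusted p = 0.0502 to 0.164), without DMSO replicate 1 for WNT11 (adjusted p = 0.126), without DMSO replicate 2 for WNT11 (adjusted p = 0.0904). With normexp background correction, WNT2B was at 0.70, MMP10 was at -1.46, MMP7 was at -3.86, MMP13 was at -3.25, EREG was at -1.60, FGF14 was at -0.49, FGF16 was at 1.15, MMP27 was at -1.98, WNT11 was at -0.30 (adjusted p = 0.0888, no longer past) and WNT7A was at 2.17. WNT2B also missed the threshold with quantile normalization, the authors' values, no filter and probe means (adjusted p = 0.0577, 0.0569, 0.0764 and 0.0506). WNT11 also missed the threshold with quantile normalization and no filter (adjusted p = 0.0744 and 0.0670).

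Crystallins were higher while photoreceptor and amacrine lists were lower. The photoreceptor median stayed negative under all 6 scalings tried and reached at most -0.60, under normexp with quantiles. That value cannot decide whether the choice of scaling contributes, which stays open. The scalings gave a median of all features from only -0.0036 to 0.081, so they could hardly have turned the list's sign. Dilution of every retinal cell type alike by lens-type RNA, as the whole cause, stays open. The median of 8 bipolar members, from -0.19 to 1.39, lay 1.49 above that of 38 photoreceptor and amacrine members (permutation p = 0.00528, Holm over 4 lists). The Müller glia median lay 1.23 above it (0.00765), while ganglion and progenitor lists did not pass (0.124 and 0.0859). Those p-values cannot decide the question, because the reference lists were picked as the lowest in these data. The permutation also shuffled genes as if they were independent. A permutation test of the spread over all 6 lists, which picked no list, missed 0.05 (p = 0.0527). Carry-over of lens tissue into the DAPT cultures may contribute: the lens membrane list had a median of 0.80, which that explanation needs, but MIP at -0.11 did not pass. A change in cell fate under DAPT stays open too and was not tested, since whole cultures give no counts of cells.

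Fibroblast, mesenchymal and matrix genes were lower. A lower share of fibroblast-type cells in the DAPT cultures may account for this, as 81.0% of the fibroblast list (17 of 21) fell, while TCF21 rose by 4.57. Fewer such cells and lower expression within them cannot be told apart, because no measurement here counts cells. An effect of DAPT on these genes themselves stays open and was not tested.

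Arrays with the same replicate number deviated together, with a correlation of 0.583 between the replicate differences of DMSO and DAPT over features, and 1304 features (113 symbol genes) differed between replicate numbers with the group as a block. Probe-specific hybridization differences are argued against, because the second probes of 10 genes that differed between replicate numbers had a median difference of 0.65 (one-sided permutation p = 2e-05), 9 of them in the direction of the first probe. Labelling, hybridization or scanning of the shared slide may contribute and stays open: 8 spike-in RNAs had an SD of 0.0987 between slides, against a median of 0.179 for draws of features of like brightness, and 0.0668 of 100000 draws had as small a spread. Different cell content of the preparations also stays open. Of the lists of other cell types, 0 of 7 differed between replicate numbers (camera adjusted p under 0.05), but missing that threshold excludes no difference. Their medians, replicate 1 minus 2, were 0.47 for endothelial, 0.29 for oligodendrocyte, 0.20 for erythroid and 0.19 for macrophage genes. Fibroblast genes were at -0.11, keratin genes at 0.022 and ciliary margin genes at 0.0021. The cell proliferation list did differ (median -0.086, camera adjusted p = 0.0461).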
